A study of Mus musculus with 20 samples.

How the data were processed

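The data are polyA RNA sequencing of 6620c1, a mouse pancreatic cancer line derived from KPCY mice, with an empty vector (EV) or with knockout of Smad4 (KO), untreated or treated with TGFb at 30 ng/ml for 48 h. Per the labels' protocols, cells were plated in wells 24 hours before treatment, RNA was extracted with a column kit and Novogene enriched mRNA and made the libraries. The aligner, the counting tool and the genome build are not given in the sources used here. The labels give 20 samples. The 12 of 6620c1 form 4 groups of 3 libraries, and the 8 of the line BMFA3V1 had no columns in the deposited tables used here and were not analysed.

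The deposited table of all genes holds raw counts per library for 54532 Ensembl genes, per the file headers and from the values, which are whole numbers. Every gene had a name, and 103 symbols were shared by more than 1 identifier, so tests ran by identifier. The identifiers and coordinates were compared with GENCODE M21 on GRCm38, where 99.9% of identifiers were found and 98.3% of those had the same start and end, though the authors' build is not stated. Per the file headers, 3 deposited comparison tables give the authors' log2 fold changes, p-values and adjusted p-values for TGFb in EV cells, TGFb in KO cells and untreated KO against EV cells. The authors' test is not named, and these tables list only part of the genes: the first 2 those with p under 0.05, the last those with adjusted p under 0.05 and at least a 2-fold change. The counts in these tables equalled those of the table of all genes in every cell, and their other 36 per-sample columns (scaled and length-scaled values) were not used.

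Libraries held 15.2 to 37.3 M counts. Counts were filtered with filterByExpr, scaled by the trimmed mean of M values (TMM) and fitted over all 12 libraries with the quasi-likelihood model of edgeR 4.0.16, 1 mean per group, with R 4.3.3. A total of 14234 genes was tested, p-values were adjusted by Benjamini-Hochberg per comparison, and an adjusted p under 0.05 was called. The comparisons were TGFb in EV cells, TGFb in KO cells, the difference between these responses (KO minus EV, an interaction contrast), and KO against EV cells without and with TGFb. CPM are counts per M of the TMM-scaled library size. The comparisons, the test, the lists, the rule for naming genes and most of the alternatives were fixed before the data were examined. The labels give each library a batch equal to its replicate number, so the numbers pair the samples, and the pairing comes from that label. In the data, 0 of 18 pairs of same-numbered libraries had deviations from their group means that correlated above 0.1 (-0.098 to 0.076). For 2 of 12 libraries, the mean correlation with libraries of the other groups was highest for their own number. The batches hold 1 library of each group, so no test within a batch can be made, and the batch entered as a block in an alternative fit.

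For genes with 0 counts in a group a bound is given as "at least" a fold, with a floor of 3 counts over that group, and for genes with 1 to 3 counts a ratio with its 95% counting interval. These cover counting error only. For other genes close to 0 in a group the fitted fold depends on the prior count, so their CPM are given.

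The genes named are Smad4, then per comparison from the 8 largest rises and 8 largest falls among called genes with at least 5 CPM in the higher group and no overlap between replicates (an overlap was allowed for the difference), leaving out predicted genes, and from each list up to 4 called members with the largest change and at least 1 CPM, or the most abundant member where none was called. Counts of some close paralogs, such as chemokines of one family, depend on how the authors assigned shared reads. The 23 gene lists were TGFb-SMAD target genes, BMP-ID target genes, TGFb family genes, mesenchymal, epithelial, extracellular matrix, actin and contractile genes, DNA replication and mitosis, p53, interferon response, antigen presentation, chemokine and cytokine, glycolysis and hypoxia, cholesterol and fatty acid synthesis, unfolded protein and ATF4 response, classical pancreatic cancer and ductal, basal and squamous, Hippo-YAP target and Wnt target genes, and markers of immune, fibroblast and stellate, endothelial, and acinar and islet cells. Each was tested against all other genes with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 23 lists of a comparison. Camera with a correlation estimated from the data was the stricter alternative. It was stricter also where the estimate lay below the preset. For mesenchymal genes in KO cells the estimate was -0.032, and the adjusted p went from 0.0096 to 0.0616. A call lost with an estimated correlation thus does not by itself show that the genes of a list were correlated. Counts of members are given over all genes and, where different, adjusted over the list alone.

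The relation between the untreated KO effect and the TGFb response of EV cells was set against 20 simulations of unchanged groups sharing the same controls. Chromosome medians used genes with a mean of at least 5 CPM. Alternatives covered scaling, filters, DESeq2 1.42.0, limma voom, the libraries in the fit, the replicate block, a fold threshold and each library or batch left out. After the data were seen, robust dispersions, voom with sample weights, correction for GC content and gene length by splines with 5 degrees of freedom, and fits without KO TGFb replicate 2 were added. The closing section gives their effects.

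The analysis was tested on simulated data with known changes at the depth of these libraries, with 1 spread per gene for all of them. KO TGFb replicate 2 raised that spread (common dispersion 0.0397 with it and 0.00399 without it). With all 12 libraries, the simulated EV libraries were therefore noisier than the real ones. For the TGFb response in EV cells it recovered 54% of genes changed 2-fold and 83% of genes changed 4-fold, with 4.9% of calls false. Without KO TGFb replicate 2 it recovered 78% and 94%, with 5.5% false. Each was a single run with 100 genes changed 2-fold and 100 changed 4-fold, while 3886 genes were called in the real EV comparison. Recovery after adjustment depends on how many genes change, so these percentages need not hold for the real data. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.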

Results

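PolyA RNA sequencing measured gene expression in 6620c1, a pancreatic cancer line from a tumour of KPCY mice, in which Cre under the Pdx1 promoter switches on mutant Kras, mutant Trp53 and a YFP reporter. Control cells carried an empty vector (EV) and were labelled wild type. The other cells were a knockout (KO) of Smad4, the SMAD that joins receptor-activated SMADs in TGFb and BMP signalling. Both kinds of cells were left untreated or were given TGFb at 30 ng/ml for 48 h, which made 4 groups of 3 libraries. The 12 libraries held 15.2 to 37.3 M counts, and 14234 genes had enough counts to be tested. Levels below are CPM (counts per M counts of the scaled library) as mean ± SD over n = 3 libraries, and log2 fold changes carry their SE. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. A further 8 samples of a line named BMFA3V1 are in the labels and were not analysed here.

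KO TGFb replicate 2 stood apart from the other libraries. It detected 14376 genes against 18133 to 19358 in the others, had 568 genes with 1 to 3 counts against 2547 to 3787, and held 1.97% mitochondrial counts against 0.527% to 0.792%. Its counts differed from those of the other KO TGFb replicates with a chi-square per degree of freedom of 217 and 185, while the other pairs of replicates gave 2.74 to 8.89, so no pair of libraries matched within sampling noise. The library stayed in the tests that follow. Because all groups shared one estimate of the spread, it also widened the spread for comparisons that it was not part of. The common dispersion was 0.0397 with it and 0.00399 without it. The count of genes for each comparison is followed by the count without it, an alternative added after the data were seen, and so are the list counts that it moved by more than 1.5 times.

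Smad4 (ENSMUSG00000024515, chromosome 18, 73639009 to 73703780 in the deposited coordinates) was low in all 6 KO libraries. It stood at 105 ± 2.92 CPM in untreated EV cells and 128 ± 6.76 CPM with TGFb, against 9.78 ± 0.54 and 9.23 ± 1.21 CPM in KO cells, or 9.33% and 7.23% of the EV level. The log2 fold change was -3.42 ± 0.11 in untreated cells (adjusted p = 3.24e-08) and -3.78 ± 0.11 with TGFb (adjusted p = 9.61e-09). For TGFb against untreated cells, Smad4 had a log2 fold change of 0.29 ± 0.10 in EV cells (adjusted p = 0.0536) and of -0.08 ± 0.11 in KO cells (adjusted p = 0.707). Without KO TGFb replicate 2 the first of these passed the threshold (adjusted p = 1.79e-04) and the second was 0.02.

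**Figure D1:**
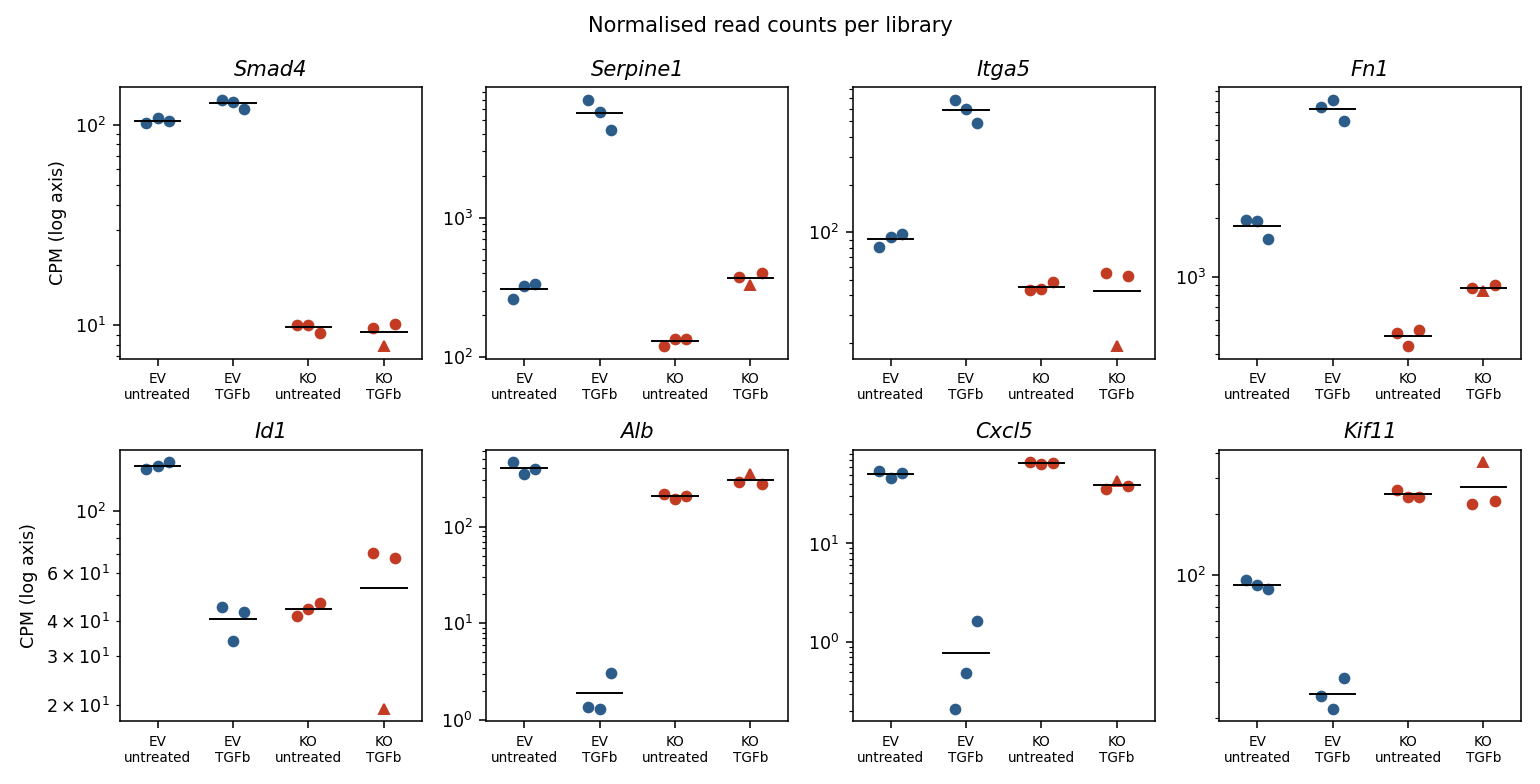
CPM per library on log axes for Smad4, Serpine1, Itga5, Fn1, Id1, Alb, Cxcl5 and Kif11 in the 4 groups, EV libraries in blue and KO libraries in red. Points are libraries, the triangle is KO TGFb replicate 2 and lines are group means, such as 5640 CPM of Serpine1 in EV cells with TGFb against 368 CPM in KO cells with TGFb.

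The first comparison asked what TGFb changes in cells with Smad4. In EV cells TGFb raised its known target genes, extracellular matrix genes and contractile genes, and lowered replication and mitosis genes. Serpine1, the plasminogen activator inhibitor, rose from 306 ± 37.9 to 5640 ± 1390 CPM, and Col7a1, the collagen of anchoring fibrils, from 1.99 ± 0.554 to 199 ± 29.0 CPM. Albumin (Alb) fell from 400 ± 58.1 to 1.91 ± 0.998 CPM, and Apoa1, the main apolipoprotein of HDL, from 35.5 ± 3.07 to 0.160 ± 0.0321 CPM. In all, 3886 genes passed, 1957 higher and 1929 lower, and 1649 of them changed at least 2-fold. Removing KO TGFb replicate 2 gave 8031, 4005 higher and 4026 lower, and they included all 3886. Scaling by library totals alone moved the median of all genes from -0.015 to -0.131 and the split to 1495 higher and 2557 lower. Without replicate 1 or 3 of every group 1386 or 1583 passed.

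Of 25 tested TGFb-SMAD target genes, 24 rose and none fell (24 rose and 1 fell adjusted over the list alone; camera adjusted p = 6.83e-29, and adjusted p = 0.0120 with an estimated correlation). Serpine1 rose by 4.20 ± 0.19 and Col7a1 by 6.63 ± 0.50 (adjusted p = 1.57e-07 and 3.84e-06). Ltbp2, of the latent TGFb binding proteins, went from 0.104 ± 0.144 to 7.74 ± 1.47 CPM. Nox4, an NADPH oxidase, was 118 times higher (95% counting interval 20.7 to 4690). Among 27 ligands, receptors and SMADs of the TGFb family, 11 rose and 5 fell, both over all genes and adjusted over the list alone (adjusted p = 0.0039). Bmp1, which encodes a procollagen protease, rose by 2.29 ± 0.16, and follistatin (Fst), an activin antagonist, went from 0.122 ± 0.111 to 2.77 ± 0.653 CPM. Of 7 tested BMP-ID target genes, 4 fell and none rose, with the same count adjusted over the list alone (adjusted p = 1.49e-04, and adjusted p = 0.0941 with an estimated correlation). Those 4 were the inhibitors of bHLH factors Id1 (146 ± 4.26 to 40.7 ± 5.84 CPM) and Id2 (217 ± 12.7 to 53.7 ± 8.85 CPM), the repressor Hey1 (6.64 ± 0.914 to 0.173 ± 0.0378 CPM), and the bHLH factor Atoh8, which fell by 4.14 ± 0.53. With KO TGFb replicate 2 left out, 24 TGFb-SMAD target genes rose and 1 fell, and 1 BMP-ID target gene rose and 5 fell. TGFb family genes had 9 higher and 3 lower without EV untreated replicate 2 or EV TGFb replicate 2, and 1 TGFb-SMAD target gene fell without EV untreated replicate 1.

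Extracellular matrix genes rose as a group, 22 of 24 tested with none lower (23 higher and 1 lower adjusted over the list alone; adjusted p = 1.38e-20). Fibronectin (Fn1) went from 1810 ± 215 to 7270 ± 923 CPM, Col12a1, a fibril-associated collagen, from 10.1 ± 1.37 to 186 ± 28.5 CPM, and the laminin chain Lama3 from 0.418 ± 0.284 to 8.19 ± 1.98 CPM. Of 17 mesenchymal genes, 10 rose and none fell, also adjusted over the list alone (adjusted p = 3.47e-05). They included Itga5, which encodes a subunit of the fibronectin receptor (2.71 ± 0.32), and Snai1, a transcription factor of epithelial-mesenchymal transition (3.03 ± 0.62, adjusted p = 0.0034). Actin and contractile genes rose in 9 of 14 cases and fell in 2 (10 and 2 adjusted over the list alone; adjusted p = 3.12e-04). Smooth muscle actin Acta2 rose (8.44 ± 0.92 to 66.0 ± 4.78 CPM), with alpha-actinin Actn1 higher by 1.23 ± 0.09 and myosin light chain kinase Mylk lower at -1.08 ± 0.08. Hippo-YAP target genes had 7 of 15 higher and none lower by either adjustment (adjusted p = 4.37e-06), including the matricellular genes Ctgf (354 ± 38.2 to 2310 ± 474 CPM) and Cyr61 (log2 fold change 2.06 ± 0.14). Wnt target and feedback genes had 4 of 8 higher and none lower by either adjustment (adjusted p = 0.0069), among them the feedback gene Axin2 (0.573 ± 0.161 to 8.40 ± 0.303 CPM) and the ligands Wnt7a (2.28 ± 0.27) and Wnt7b (2.18 ± 0.37). With KO TGFb replicate 2 left out, 23 matrix genes rose and 1 fell, 12 mesenchymal genes rose and 1 fell, and 9 Hippo-YAP target genes rose and 1 fell.

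DNA replication and mitosis genes fell in 29 of 34 cases and rose in 1 (32 and 1 adjusted over the list alone; adjusted p = 4.22e-16). The licensing factor Cdc6 went from 17.8 ± 0.163 to 3.85 ± 0.939 CPM, the helicase subunit Mcm5 from 84.0 ± 2.66 to 26.2 ± 3.15 CPM, the spindle kinesin Kif11 from 90.2 ± 4.52 to 26.3 ± 4.59 CPM, and survivin (Birc5) from 52.3 ± 1.81 to 15.3 ± 2.06 CPM. Glycolysis and hypoxia genes fell in 14 of 23 cases and rose in 3 (16 and 3 adjusted over the list alone; adjusted p = 1.78e-05, and adjusted p = 0.191 with an estimated correlation). Among them were the prolyl hydroxylase Egln3 (-2.07 ± 0.17), the pyruvate dehydrogenase kinase Pdk1 (-1.26 ± 0.08) and lactate dehydrogenase Ldha (1060 ± 14.3 to 462 ± 20 CPM). Among 19 genes of the unfolded protein and ATF4 response, 6 fell and none rose (7 and 1 adjusted over the list alone; adjusted p = 0.0383, and adjusted p = 0.349 with an estimated correlation). They included Psat1 of serine synthesis (-1.61 ± 0.12) and the cystine transporter Slc7a11 (-1.18 ± 0.17). Chemokine and cytokine genes went both ways, with 6 of 19 higher and 6 lower (7 and 7 adjusted over the list alone; adjusted p = 0.0479). That call was lost with an estimated correlation (adjusted p = 0.0941) and with the replicate number as a block (adjusted p = 0.202). The neutrophil chemokines Cxcl5 (51.0 ± 4.14 to 0.777 ± 0.759 CPM) and Cxcl15 and the chemokine Ccl20 (5.64 ± 0.0742 to 0.160 ± 0.113 CPM) fell, and the cytokine Il11 rose from 0.0596 ± 0.103 to 27.6 ± 12.3 CPM. The 1 higher replication call was lost without EV untreated replicate 1 or 3 or EV TGFb replicate 1 or 2. For the unfolded protein and ATF4 response, 2 genes rose and 13 fell without KO TGFb replicate 2, 3 fell without EV untreated replicate 3 or EV TGFb replicate 2, and 1 rose without KO TGFb replicate 1 or 3.

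Other genes among the largest rises were scarcely counted in untreated EV cells. Prss46, of the serine proteases, had no counts there and was at least 351-fold higher with TGFb, the angiopoietin Angpt4 was 3580 times higher (95% counting interval 642 to 141000), and coagulation factor F13a1 went from 0.102 ± 0.0906 to 32.2 ± 4.20 CPM. Sptssb, a small subunit of serine palmitoyltransferase, fell from 40.0 ± 7.68 to 0.197 ± 0.0962 CPM. The remaining lists did not pass as groups. Among 18 epithelial genes, 4 rose and 5 fell (4 and 7 adjusted over the list alone; adjusted p = 0.0827, and 0.0105 without KO TGFb replicate 2, or 0.0643 there with an estimated correlation), with the tight junction genes Cldn4 up (0.102 ± 0.0906 to 11 ± 2.55 CPM) and Tjp3 down at -2.13 ± 0.23. Among 9 basal and squamous genes, 4 rose and 3 fell by either adjustment (adjusted p = 0.127, and 0.0065 without KO TGFb replicate 2, or 0.0643 there with an estimated correlation), including basal keratin Krt14 (1.44 ± 0.625 to 23.6 ± 3.85 CPM), the laminin chain Lamb3 (2.93 ± 0.29) and involucrin Ivl (4.48 ± 0.359 to 0.378 ± 0.111 CPM). Of 18 classical pancreatic cancer and ductal genes, 4 rose and 8 fell (4 and 9 adjusted over the list alone; adjusted p = 0.243). Cathepsin E (Ctse) and the ductal factor Sox9 rose by 2.65 ± 0.16 and 2.21 ± 0.13, and Anxa10 stood at -3.37 ± 0.31. Cholesterol and fatty acid synthesis genes had 5 of 26 higher and 3 lower by either adjustment (adjusted p = 0.161), including Hmgcr (0.96 ± 0.07), the rate-limiting enzyme of cholesterol synthesis, and Acaca (0.76 ± 0.08) of fatty acid synthesis. Of 20 p53, CDK inhibitor and apoptosis genes 2 rose and 2 fell by either adjustment (adjusted p = 0.980), the CDK inhibitor Cdkn2c at -1.75 ± 0.20 among them. Of 22 interferon response genes 2 rose, Stat2 (0.64 ± 0.11) among them, and 1 fell by either adjustment (adjusted p = 0.719). Of 13 antigen presentation genes 1 rose and 2 fell, and none passed adjusted over the list alone (adjusted p = 0.685). In the fit without KO TGFb replicate 2 the genes higher and lower were 4 and 13 for epithelial genes, 13 and 5 for cholesterol and fatty acid synthesis, 10 and 8 for p53 genes, 4 and 4 for interferon response and 3 and 7 for antigen presentation. Without EV untreated replicate 1, 1 interferon response gene, no antigen presentation gene and 3 higher cholesterol genes were left. Without EV untreated replicate 2, 1 p53 gene rose and 1 fell.

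Few markers of other cell types were counted highly enough to test. In EV cells with TGFb, 1 of 3 immune markers rose and 1, the macrophage receptor Csf1r (-1.24 ± 0.15), fell (1 and 2 adjusted over the list alone; adjusted p = 0.305). Of 5 fibroblast and stellate cell markers 2 rose, among them the collagen Col15a1 (2.09 ± 0.17), and none fell (2 and 1 adjusted over the list alone; adjusted p = 0.261). Of 5 endothelial markers 2 rose by either adjustment, one being Cdh5, the cadherin of endothelial junctions, at 0.142 ± 0.0933 and then 6.36 ± 1.49 CPM (adjusted p = 0.0671 for the list). Neither of 2 acinar and islet markers passed (adjusted p = 0.980 for the list), and the acinar factor Bhlha15 stood at 0.697 ± 0.271 and 0.439 ± 0.368 CPM. In the fit without KO TGFb replicate 2, 1 immune marker was higher and 2 lower, 2 fibroblast markers were higher and 2 lower, and 2 endothelial markers were higher and 1 lower. These counts moved by 1 gene without some other single libraries.

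**Figure D2:**
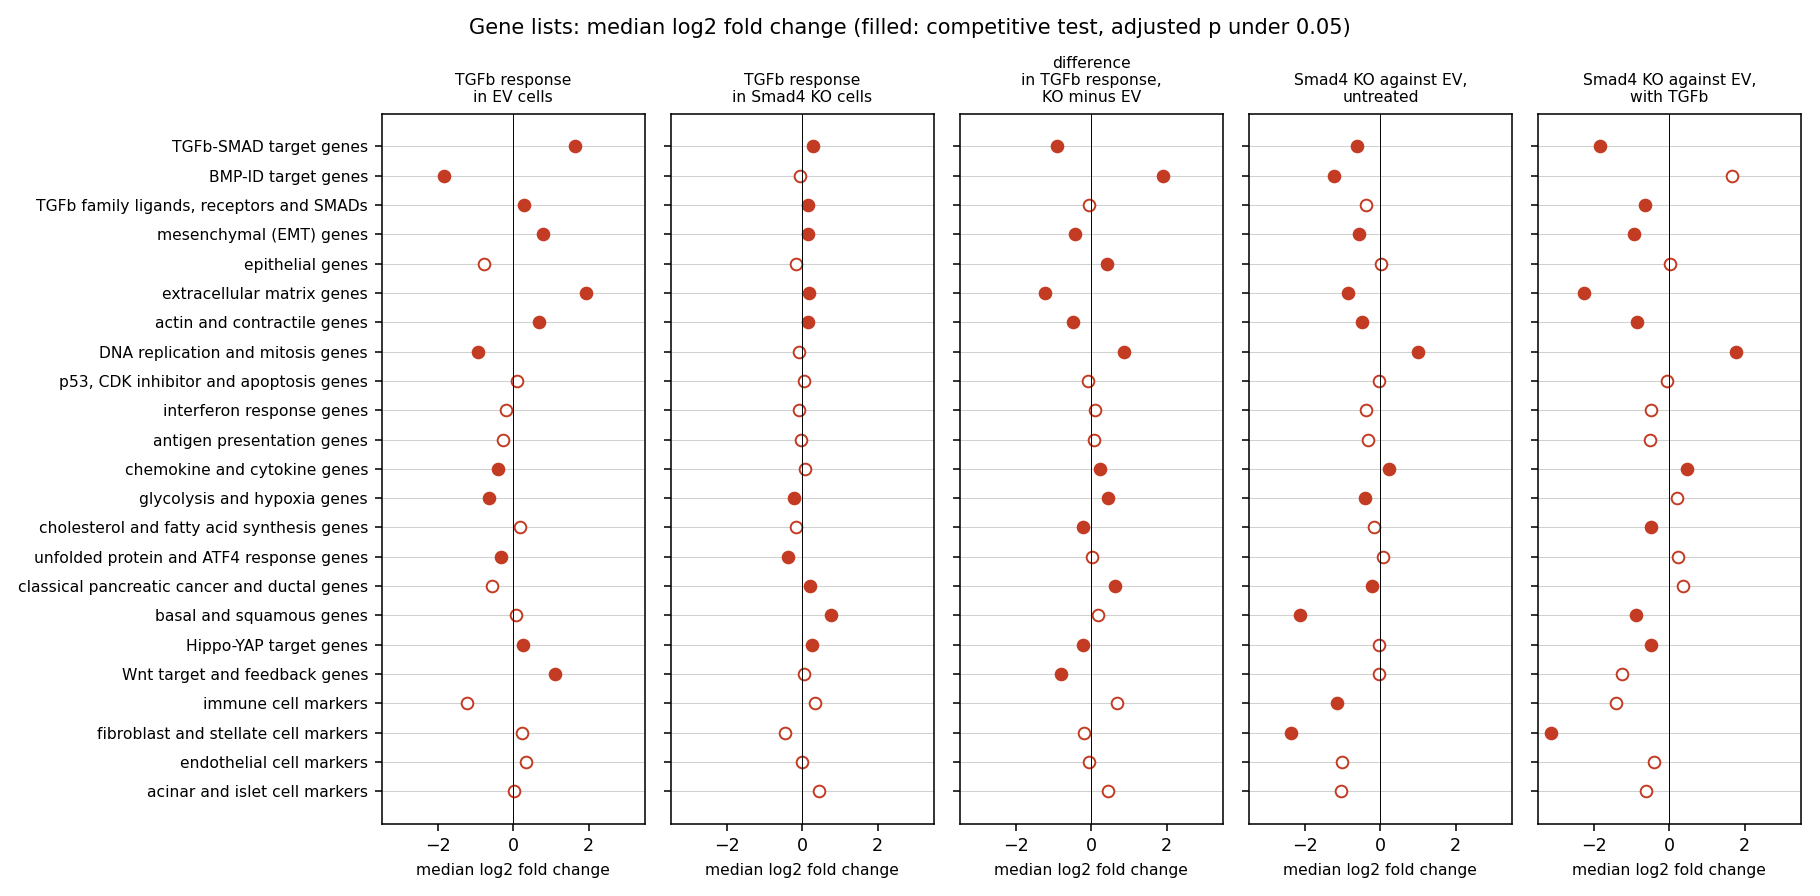
Median log2 fold change of the tested members of 23 gene lists (vertical axis) in the 5 comparisons. Filled points passed the camera test, for example the TGFb-SMAD target genes at 1.63 in EV cells and 0.29 in KO cells (1.54 and 0.54 without KO TGFb replicate 2).

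The second comparison asked what TGFb changes in Smad4 KO cells. A small set of genes rose in KO cells, among them members of the TGFb-SMAD list, and few fell. Serpine1 rose from 130 ± 9.15 to 368 ± 35.0 CPM, Pmepa1, a feedback inhibitor of TGFb signalling, from 56.0 ± 3.01 to 144 ± 16.5 CPM, and the type I receptor Tgfbr1 from 71.5 ± 0.78 to 184 ± 34.6 CPM. Ctse rose from 2.38 ± 0.656 to 14.8 ± 1.14 CPM. In all, 145 genes passed, 126 higher and 19 lower, 67 of them at least 2-fold. With the replicate number as a block 72 passed, 68 higher and 4 lower. Removal of KO TGFb replicate 2 kept all 145 calls and gave 1344, 805 higher and 539 lower. Leaving out KO untreated replicate 1, 2 or 3 left 47, 45 or 48 genes. With only the libraries of these groups in the fit, or without replicate 1 or 3 of every group, 1 gene passed, Csdc2. Serpine1 and Pmepa1 (adjusted p = 0.0553 each with only these libraries), Tgfbr1 (0.1100) and Ctse (0.0553) did not.

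The largest rises included cathepsin W (Ctsw, 0.401 ± 0.118 to 9.33 ± 5.36 CPM), the cold-shock RNA-binding protein Csdc2 (3.32 ± 0.17, adjusted p = 1.04e-05), the calcium-activated potassium channel Kcnn3 (2.83 ± 0.21), cardiac troponin T (Tnnt2, 12.1 ± 1.24 to 63.7 ± 25.3 CPM), the solute carrier Slc17a4 (2.07 ± 0.14) and Ccbe1, a secreted calcium-binding protein (1.97 ± 0.19). Of 25 TGFb-SMAD target genes 6 rose and none fell (11 and 0 adjusted over the list alone; adjusted p = 2.67e-14, and adjusted p = 0.0598 with an estimated correlation). Serpine1 stood at 1.5 ± 0.17, Pmepa1 at 1.37 ± 0.12 and Tgfbr1 at 1.36 ± 0.13. Of 24 extracellular matrix genes 3 rose and none fell (5 and 0 adjusted over the list alone; adjusted p = 1.68e-04, and adjusted p = 0.222 with an estimated correlation). Of 17 mesenchymal genes 1, Fn1, rose by either adjustment and none fell (adjusted p = 0.0096, and adjusted p = 0.0616 with an estimated correlation). Fn1 went from 493 ± 48.2 to 875 ± 27.5 CPM (adjusted p = 0.0087), a call lost without KO untreated replicate 1 (adjusted p = 0.0535) or 2 (adjusted p = 0.0662). Of 27 TGFb family genes 1, Tgfbr1, rose and none fell (5 and 0 adjusted over the list alone; adjusted p = 0.0033, and adjusted p = 0.0470 with an estimated correlation). With the replicate block as well, the TGFb family call was lost (adjusted p = 0.1228). None of 14 contractile genes passed (3 rose adjusted over the list alone; adjusted p = 0.0389, and adjusted p = 0.114 with an estimated correlation). Nor did any of 15 Hippo-YAP target genes (5 rose adjusted over the list alone; adjusted p = 0.0024, and adjusted p = 0.0616 with an estimated correlation). The member counts of these lists depended on single libraries. Leaving out KO TGFb replicate 2 gave 19 of 26 TGFb-SMAD target genes higher, 10 of 24 matrix, 6 of 17 mesenchymal, 4 of 14 contractile and 9 of 15 Hippo-YAP target genes, with none lower, and 9 of 27 TGFb family genes higher with 2 lower. Leaving out KO untreated replicate 1, 2 or 3 gave 3 TGFb-SMAD target genes in each case and 0, 0 or 1 matrix genes, and 1 matrix gene passed without KO TGFb replicate 3. Without EV TGFb replicate 3, 1 Hippo-YAP target gene passed as higher.

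Basal and squamous genes had 2 of 9 higher and none lower (3 and 0 adjusted over the list alone; adjusted p = 1.56e-04), including plakophilin Pkp1 of desmosomes (0.913 ± 0.373 to 3.41 ± 0.30 CPM). Classical pancreatic cancer and ductal genes had 1 of 18 higher, Ctse, and none lower (2 and 0 adjusted over the list alone; adjusted p = 5.27e-04). The basal and classical lists passed with an estimated correlation (adjusted p = 0.0330 each), but not together with the replicate block (0.1228 each). Unfolded protein and ATF4 response genes stood lower as a group (adjusted p = 0.0025, and adjusted p = 0.251 with an estimated correlation), though none of 19 passed over all genes (1 rose and 4 fell adjusted over the list alone). Glycolysis and hypoxia genes did too (adjusted p = 0.0219, with no gene of 23 past either adjustment), a call lost with an estimated correlation (adjusted p = 0.516) and without KO TGFb replicate 2 (adjusted p = 0.132). DNA replication and mitosis genes had no gene of 34 past either adjustment (adjusted p = 0.0583), and the list passed with the replicate block (adjusted p = 0.0331, and adjusted p = 0.5457 with an estimated correlation) and without KO TGFb replicate 2 (adjusted p = 1.97e-06, and adjusted p = 0.2619 with an estimated correlation). The iron-binding lipocalin Lcn2 fell from 8.65 ± 0.854 to 3.36 ± 0.118 CPM. The neutrophil chemokines Cxcl1 (9.53 ± 1.05 to 3.82 ± 0.543 CPM, adjusted p = 0.0156) and Cxcl3 (38.5 ± 1.01 to 15.9 ± 2.73 CPM, adjusted p = 0.0274) fell, and these were the only lower calls among 19 chemokine and cytokine genes (1 rose and 2 fell adjusted over the list alone; adjusted p = 0.172 for the list, and 1.67e-04 without KO TGFb replicate 2). Both calls were lost without KO TGFb replicate 1 (adjusted p = 0.0564 and 0.0713) and without any of the KO untreated libraries (up to 0.108 for Cxcl1 and 0.148 for Cxcl3), and that of Cxcl3 also without EV untreated replicate 1, 2 or 3 or EV TGFb replicate 2 (0.0548 to 0.0628). Without KO TGFb replicate 2 the BMP-ID list turned from lower (adjusted p = 0.984) to higher (adjusted p = 0.0093), the Wnt list passed as higher (adjusted p = 0.0122) and the cholesterol and fatty acid synthesis list as lower (adjusted p = 0.0224). These 3 calls were lost in that fit with an estimated correlation (adjusted p = 0.0747, 0.0830 and 0.4026). Of 5 fibroblast and stellate cell markers 1, Col15a1, rose by either adjustment (1.81 ± 0.17; adjusted p = 0.481 for the list). In the fit without KO TGFb replicate 2 the genes higher and lower were 4 and 2 for classical genes, 1 and 7 for the unfolded protein and ATF4 response, 1 and 5 for glycolysis, 0 and 8 for replication and mitosis, 2 and 6 for chemokines and 1 and 1 for fibroblast markers. Of the basal genes, 1 passed when any 1 of the KO untreated libraries or KO TGFb replicate 3 was left out.

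Most genes that TGFb called in KO cells were also called in EV cells. Of the 126 higher in KO cells 108 were also higher in EV cells, where 17.3 would overlap if the lists were independent, and of the 19 lower 16 were also lower, where 2.6 would. No library is shared between these comparisons. Another 3 genes rose in KO cells and fell in EV cells, and none did the opposite. Genes higher in EV cells had a median log2 fold change of 0.80 there and 0.14 in KO cells, and genes lower in EV cells had -0.91 and -0.13. These medians were 0.50 and 0.09, and -0.55 and -0.10, without KO TGFb replicate 2. Across all tested genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.295 and a Spearman correlation of 0.262. Without KO TGFb replicate 2, 645 genes were higher in both (221.6 if independent) and 415 lower in both (149.1 if independent), while 70 were lower in EV and higher in KO cells and 17 the opposite way.

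**Figure D3:**
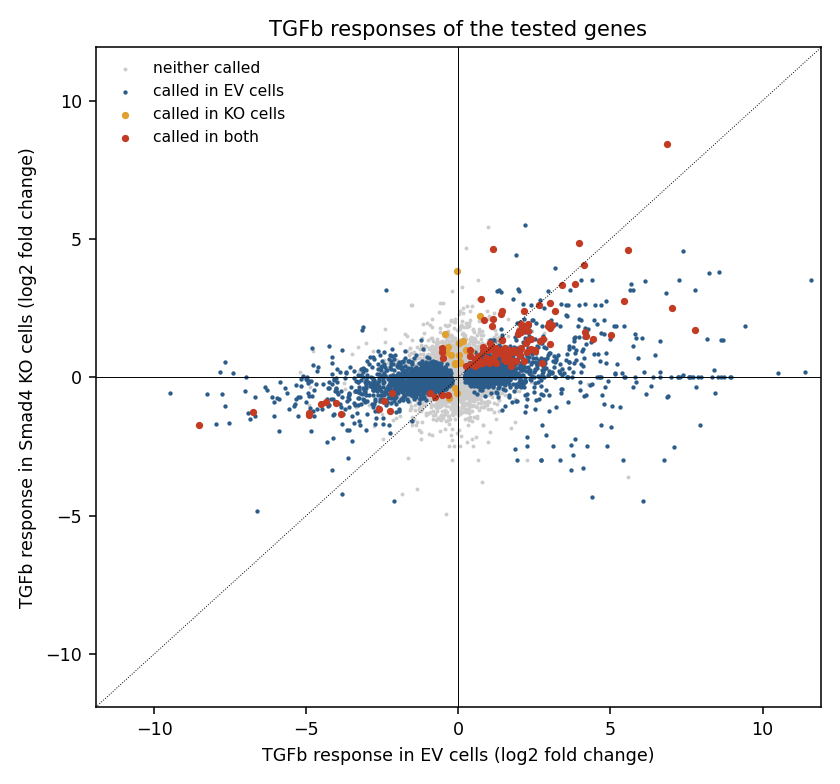
Log2 fold change with TGFb in EV cells (horizontal) and in Smad4 KO cells (vertical) for the 14234 tested genes, with the dotted line where both are equal. Points in red are the 127 genes called in both, in blue those called in EV cells and in orange those called in KO cells.

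The third comparison tested each gene for a difference between the TGFb responses, KO minus EV. Genes that fell strongly in EV cells and stayed high in KO cells were among the large positive differences, and matrix and TGFb target genes were among the negative ones. Alb stood at 205 ± 12 CPM in untreated KO cells and 302 ± 39.4 CPM with TGFb, so that its response differed by 8.24 ± 0.37 (adjusted p = 2.25e-06). Apoa1 (7.14 ± 0.35), Sptssb (6.64 ± 0.41) and Hal, histidine ammonia-lyase, also differed positively. Hal stood at 5.38 ± 1.36 and 0.0593 ± 0.0654 CPM in EV cells without and with TGFb, and at 14.9 ± 1.11 and 10.8 ± 1.62 CPM in KO cells. Col7a1 stayed at 0.967 ± 0.0129 and 0.978 ± 0.85 CPM in KO cells, and its response differed by -6.45 ± 0.72 (adjusted p = 2.88e-04). In all, 1618 genes passed, 910 positive and 708 negative, 903 of them at least 2-fold, and scaling by library totals alone gave 1183 and 512. Leaving out KO TGFb replicate 2 gave 5088, 2566 positive and 2522 negative, including all 1618. Without EV TGFb replicate 1 or KO untreated replicate 3 1073 or 1063 passed, and without replicate 1 or 3 of every group 116 or 230.

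TGFb-SMAD target genes responded less in KO cells, with 14 of 25 negative and 1 positive, the CDK inhibitor Cdkn1a at 1.33 ± 0.22 (21 and 1 adjusted over the list alone; adjusted p = 2.81e-17, and adjusted p = 0.0301 with an estimated correlation). With the replicate block as well, that list call was lost (adjusted p = 0.0862). With the block and an estimated correlation together, none of the 13 list calls of the difference held (lowest adjusted p = 0.0641). The block at the preset correlation kept 12 of the 13. Serpine1 differed by -2.70 ± 0.24, Ltbp1 of the latent TGFb binding proteins by -2.22 ± 0.11 and Fstl3, an activin antagonist, by -2.22 ± 0.40. For extracellular matrix genes 12 of 24 were negative and none positive (20 and 0 adjusted over the list alone; adjusted p = 1.44e-16), including tenascin (Tnc, 0.380 ± 0.18 and 0.256 ± 0.224 CPM in KO cells and 6.86 ± 0.724 and 71.6 ± 11.6 CPM in EV cells), Col12a1 (-2.99 ± 0.35) and Fn1 (-1.18 ± 0.17). Mesenchymal genes had 5 of 17 negative and none positive by either adjustment (adjusted p = 0.0011), Itga5 at -2.80 ± 0.43 among them, and contractile genes 4 of 14 negative and 1 positive (5 and 2 adjusted over the list alone; adjusted p = 0.0045), with Acta2 at -2.86 ± 0.27 and Mylk at 1.24 ± 0.12. Hippo-YAP target genes had 5 of 15 negative and none positive (7 and 1 adjusted over the list alone; adjusted p = 2.11e-04), with Ctgf at -2.06 ± 0.21 and Cyr61 at -1.56 ± 0.19. Wnt target and feedback genes had 1 of 8 negative, Wnt7b (-2.21 ± 0.51), and none positive (4 and 0 adjusted over the list alone; adjusted p = 0.0228, and adjusted p = 0.0725 with an estimated correlation). The Wnt7b call was lost without EV untreated replicate 1 (adjusted p = 0.0544) or EV TGFb replicate 1 (adjusted p = 0.0517). Cholesterol and fatty acid synthesis genes had 4 of 26 negative and none positive by either adjustment (adjusted p = 0.0094, and adjusted p = 0.131 with an estimated correlation), Hmgcr at -1 ± 0.10 among them. The TGFb family list had an adjusted p of 0.0884, and of 0.0270 without KO TGFb replicate 2 (adjusted p = 0.2224 with an estimated correlation). Leaving out KO TGFb replicate 2 gave 22 negative and 1 positive for both TGFb-SMAD target and matrix genes, 10 and 0 for mesenchymal, 11 and 2 for contractile, 7 and 3 for Hippo-YAP target, 4 and 0 for Wnt and 13 and 2 for cholesterol genes. Matrix genes had 7 negative without EV untreated replicate 1 or EV TGFb replicate 1, and mesenchymal genes 3 without KO untreated replicate 2. Wnt genes had 2 negative without KO untreated replicate 3, KO TGFb replicate 1 or KO TGFb replicate 3. Contractile genes had 2 positive without KO TGFb replicate 3, and Hippo-YAP target genes 1 without EV TGFb replicate 3 or KO TGFb replicate 1.

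Replication and mitosis genes differed positively, 19 of 34 with none negative (26 and 1 adjusted over the list alone; adjusted p = 2.00e-15). Kif11, which fell in EV cells, stood at 250 ± 11.8 and 272 ± 76.1 CPM in KO cells (difference 1.90 ± 0.25), with Birc5 at 1.92 ± 0.33 and Cdc6 at 1.73 ± 0.27. BMP-ID target genes had 4 of 7 positive and none negative by either adjustment (adjusted p = 3.88e-06), namely Atoh8 (4.89 ± 0.71), Hey1 (4.51 ± 0.42), Id2 (1.90 ± 0.21) and Id1 (2.10 ± 0.50, adjusted p = 0.0201). The Id1 call was lost without EV untreated replicate 3, EV TGFb replicate 2 or any of the 3 KO untreated libraries (adjusted p = 0.0519 to 0.0639). Classical pancreatic cancer and ductal genes had 7 of 18 positive and 2 negative by either adjustment (adjusted p = 0.0013), such as Anxa10 (3.24 ± 0.42) and the mucin Muc1 (2.64 ± 0.31), against Sox9 at -1.98 ± 0.18. Glycolysis and hypoxia genes had 6 of 23 positive and 1 negative (11 and 3 adjusted over the list alone; adjusted p = 8.24e-04, and adjusted p = 0.254 with an estimated correlation). Egln3 stood at 2.12 ± 0.24 and Pdk1 at 0.99 ± 0.12. Chemokine and cytokine genes had 6 of 19 positive and 2 negative (6 and 4 adjusted over the list alone; adjusted p = 0.0072, and adjusted p = 0.0764 with the replicate block). Cxcl5 stood at 5.22 ± 0.51 and Ccl20 at 5.16 ± 0.85. Epithelial genes had 4 of 18 positive, the tight junction gene Ocln (1.56 ± 0.19) among them, and 1 negative (5 and 1 adjusted over the list alone; adjusted p = 0.0258, and adjusted p = 0.241 with an estimated correlation). Their median was 0.41 while their mean was -0.02, and without KO TGFb replicate 2 these were 0.80 and 0.34. Leaving out KO TGFb replicate 2 gave 29 positive and 1 negative for replication genes, 7 and 0 for BMP-ID target genes, 16 and 3 for glycolysis, 9 and 5 for chemokines and 9 and 3 for epithelial genes. The 1 negative epithelial call of the full fit was kept without KO TGFb replicate 2, EV TGFb replicate 3 or KO untreated replicate 1 and lost with any 1 of the other libraries left out. Of the 2 negative chemokine calls 1 was lost without EV untreated replicate 1 or 2, any EV TGFb library, KO untreated replicate 1 or 2, or KO TGFb replicate 3. Without KO TGFb replicate 1 or 3, 1 replication gene was negative.

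The fourth comparison asked how KO cells differed from EV cells before any TGFb was added. The labels do not say whether either kind of cells was a single clone, so the values compare these cells and not the loss of Smad4 alone. Untreated KO cells had lower levels of basal and squamous genes and higher levels of replication and mitosis genes. Id3, an inhibitor of bHLH factors, stood at 40.4 ± 0.937 CPM in EV cells and 1.37 ± 0.336 CPM in KO cells, and Ctse at 62.0 ± 4.85 and 2.38 ± 0.656 CPM. The helicase Hells stood at 48.8 ± 2.24 and 187 ± 3.96 CPM. In all, 4740 genes passed, 2234 higher and 2506 lower in KO cells, 1757 of them at least 2-fold. A fit without KO TGFb replicate 2 gave 9047, 4364 higher and 4683 lower, and fits without replicate 1 or 3 of every group 1774 or 1612.

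Several genes were counted in 1 of the 2 kinds of cells and not in the other. Plagl1, a zinc finger factor, Afap1l1, Ttc9 and Rftn1, a lipid raft protein, had no counts in untreated KO cells and were at least 371-fold, 319-fold, 205-fold and 143-fold lower there. Dapk1, a death-associated kinase, had no counts in EV cells and was at least 219-fold higher in KO cells, and the homeobox factor Mkx was 866 times higher (95% counting interval 155 to 34200). The zinc finger gene Zfp532 stood at 0.0901 ± 0.0423 CPM in EV cells and 24.9 ± 0.323 CPM in KO cells, and Micu2, a regulator of mitochondrial calcium uptake, at 0.15 ± 0.044 and 33.4 ± 0.869 CPM.

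Replication and mitosis genes were higher in KO cells in 32 of 34 cases and lower in none by either adjustment (adjusted p = 1.97e-18), such as Hells (1.94 ± 0.32), the ribonucleotide reductase subunit Rrm2 (1.74 ± 0.10) and cyclin Ccne1 (1.49 ± 0.21). Extracellular matrix genes were lower in 14 of 24 cases and higher in 3 (15 and 4 adjusted over the list alone; adjusted p = 2.55e-04, and adjusted p = 0.208 with an estimated correlation). Tnc (-4.10 ± 0.39), Lamb3 (-3.76 ± 0.31) and Col12a1 (-2.88 ± 0.25) were lower, and the proteoglycan versican (Vcan) was higher (0.376 ± 0.161 CPM in EV and 5.49 ± 1.20 CPM in KO cells). TGFb-SMAD target genes were lower in 11 of 25 cases and higher in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.0031, and adjusted p = 0.302 with an estimated correlation). Lower were the AP-1 member Junb at -1.80 ± 0.43, Pmepa1 at -1.66 ± 0.12, Tgfbr1 at -1.38 ± 0.13 and Ctgf at -1.25 ± 0.15. Mesenchymal genes were lower in 8 of 17 cases and higher in 1, N-cadherin (Cdh2, 1.05 ± 0.20), by either adjustment (adjusted p = 0.0121, and adjusted p = 0.0705 with an estimated correlation), with Fn1 at -1.88 ± 0.13. Contractile genes were lower in 7 of 14 cases and higher in none (8 and 0 adjusted over the list alone; adjusted p = 0.0121, and adjusted p = 0.0705 with an estimated correlation). Acta2 stood at -1.86 ± 0.19 and tropomyosin Tpm1 at -0.81 ± 0.13. Basal and squamous genes were lower in 7 of 9 cases and higher in none (8 and 0 adjusted over the list alone; adjusted p = 4.54e-05), with Krt14 61.9 times lower (95% counting interval 16.7 to 519) and the serpin Serpinb5 at -2.81 ± 0.29. BMP-ID target genes were lower in 4 of 7 cases, Id3 (-4.85 ± 0.24), Atoh8 (-3.23 ± 0.49) and Id1 (-1.72 ± 0.36) among them, and higher in 1 by either adjustment (adjusted p = 0.0205). That call was lost with an estimated correlation (adjusted p = 0.264) and with the replicate block (adjusted p = 0.122). In the fit without KO TGFb replicate 2, 18 TGFb-SMAD target genes were lower and 2 higher, 13 mesenchymal genes lower and 1 higher, 13 contractile genes lower and none higher, and 4 BMP-ID target genes lower and 2 higher. Contractile genes had 4 lower with EV untreated replicate 2 or any 1 KO untreated library left out, and mesenchymal genes 5 lower without KO untreated replicate 3. The higher TGFb-SMAD call was lost with any 1 of the other libraries left out. The replication and basal lists passed with an estimated correlation (adjusted p = 0.0233 each), but not together with the replicate block (0.0712 each) or without KO TGFb replicate 2 (0.0892 each).

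Glycolysis and hypoxia genes were lower in 13 of 23 cases and higher in 2 by either adjustment (adjusted p = 0.0121, and adjusted p = 0.384 with an estimated correlation). The collagen prolyl hydroxylase P4ha1 stood at -1.24 ± 0.12 and the lactate transporter Slc16a3 at 2.08 ± 0.45. Classical pancreatic cancer and ductal genes were lower in 8 of 18 cases and higher in 2 by either adjustment (adjusted p = 0.0451, with an estimated correlation adjusted p = 0.124, with the replicate block adjusted p = 0.113), with Ctse at -4.68 ± 0.19 and the forkhead factor Foxa1 at 2.07 ± 0.26. Chemokine and cytokine genes were higher in 6 of 19 cases and lower in 1 by either adjustment (adjusted p = 0.0451), Ccl20 (2.40 ± 0.45) and Cxcl1 (1.52 ± 0.22) among them. That call was lost with an estimated correlation (adjusted p = 0.124), with the replicate block (adjusted p = 0.0596) and without KO TGFb replicate 2 (adjusted p = 0.0986). The TGFb family list, with 12 of 27 lower and 4 higher (13 and 5 adjusted over the list alone; adjusted p = 0.0576), passed with the replicate block (adjusted p = 0.0484) and without KO TGFb replicate 2 (adjusted p = 0.0402), and so did the Hippo-YAP list without that library (adjusted p = 0.0810 with it and 0.0390 without). These calls were lost with an estimated correlation (adjusted p = 0.1471 for the TGFb family with the block, and 0.2665 for both lists without that library). Of the TGFb family genes, the ligand Bmp2 was higher in KO cells at 2.06 ± 0.20. Antigen presentation genes were lower in 6 of 13 cases and higher in 2 by either adjustment (adjusted p = 0.130 for the list), with the peptide transporter Tap2 at 5.69 ± 0.418 CPM in EV and 0.595 ± 0.065 CPM in KO cells. Psat1 was higher at 1.19 ± 0.12 among unfolded protein and ATF4 response genes (5 of 19 higher and 1 lower by either adjustment; adjusted p = 0.266). In the fit without KO TGFb replicate 2, 10 chemokine genes were higher and 4 lower, 7 TGFb family genes higher and 15 lower, and 9 unfolded protein and ATF4 response genes higher and 5 lower. With any 1 of the EV or KO untreated libraries left out, the higher genes were 1 for the TGFb family, 1 for glycolysis and 2 or 3 for the unfolded protein and ATF4 response, and lower antigen presentation genes were 3 without KO untreated replicate 1. Higher antigen presentation genes were 0 without KO untreated replicate 2, and 1 without KO untreated replicate 3, EV TGFb replicate 2 or any 1 EV untreated library.

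Of 4 lists of markers of other cell types, those of fibroblasts and immune cells passed as lower in untreated KO cells. Endothelial markers (1 of 5 lower by either adjustment, adjusted p = 0.464) and acinar and islet markers (1 of 2 lower by either adjustment, adjusted p = 0.772) did not pass. Fibroblast and stellate cell markers were lower in 4 of 5 cases and higher in none by either adjustment (adjusted p = 4.34e-05), with desmin (Des) at 9.19 ± 0.885 CPM in EV and 0.409 ± 0.0827 CPM in KO cells, the PDGF receptor Pdgfrb at 3.93 ± 0.264 and 0.742 ± 0.342 CPM and Col15a1 at 13.3 ± 1.49 and 3.05 ± 0.176 CPM. The fibroblast list passed with an estimated correlation (adjusted p = 0.0388), but not together with the replicate block (0.1239). Nor did it together with removal of KO TGFb replicate 2, where the lowest adjusted p of any list was 0.0892. The 3 tested immune cell markers were lower by either adjustment (adjusted p = 0.0451), Csf1r at 14.5 ± 1.34 and 6.50 ± 0.772 CPM among them. That call was lost with an estimated correlation (adjusted p = 0.132) and without KO TGFb replicate 2 (adjusted p = 0.0814). In that fit 2 endothelial markers were lower. The acinar and islet call was lost without EV untreated replicate 3 or KO untreated replicate 1 or 2.

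The KO effect also followed chromosomes. On chromosome 19, 92.8% of 375 genes with a mean of at least 5 CPM were higher in untreated KO cells, with a median log2 fold change of 0.75, and the medians of the 3 KO libraries against the EV mean ran from 0.74 to 0.77. Chromosome 9 had a median of -0.56 and 12.7% of genes higher, chromosome 10 a median of -0.29, chromosome 3 of 0.35 and chromosome 17 of 0.28. With TGFb the KO effect had medians of 0.75 on chromosome 19 and -0.59 on chromosome 9. The values of KO against EV cells given here for genes and lists were not adjusted for these shifts. Those of genes on a shifted chromosome, including list members, may therefore hold the shift as well.

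**Figure D4:**
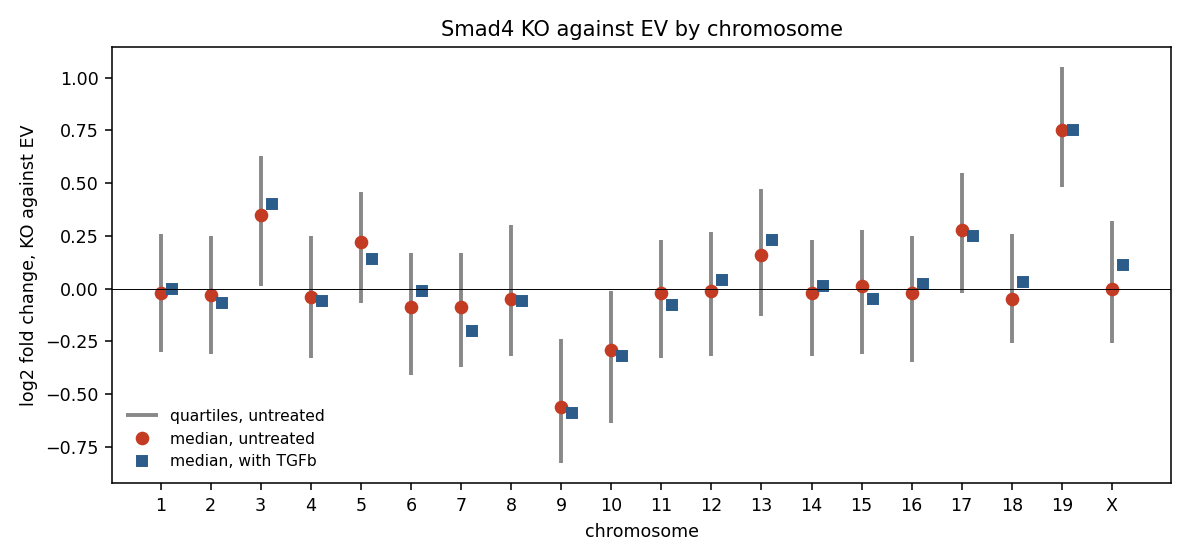
Median log2 fold change of Smad4 KO against EV cells by chromosome, for untreated cells (circles, with bars from the lower to the upper quartile of genes) and with TGFb (squares). Chromosome 19 lies at 0.75 in both states and chromosome 9 at -0.56 and -0.59.

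The TGFb response of EV cells and the untreated KO effect share the EV untreated libraries, and 3 libraries cannot be split into parts that each keep at least 2. In a fit of these 9 libraries the log2 fold changes correlated at -0.089 (Pearson) and -0.137 (Spearman) across genes, where simulated unchanged groups against the same controls gave 0.508 and 0.454. The simulated groups hold no true change, so their correlations are set by noise in the shared controls and are not the values expected here. The covariance was -0.106 against a simulated 0.0214, a difference of -0.127. Genes higher with TGFb in EV cells and lower in KO cells numbered 1832 (1293 if the lists were independent), and genes lower with TGFb and higher in KO cells 1591 (1209.6 if independent), while 897 were higher in both (1208.4) and 1256 lower in both (1294.3).

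The fifth comparison set KO cells against EV cells when both had received TGFb. KO cells with TGFb held far less of the matrix, contractile and TGFb target transcripts and more of the replication and mitosis transcripts. Serpine1 stood at 5640 ± 1390 CPM in EV and 368 ± 35.0 CPM in KO cells, Fn1 at 7270 ± 923 and 875 ± 27.5 CPM, and Acta2 at 66.0 ± 4.78 and 2.56 ± 0.862 CPM. Cdc6 stood at 3.85 ± 0.939 CPM in EV and 35.1 ± 8.08 CPM in KO cells, and Ccl20 at 0.160 ± 0.113 and 31.3 ± 25.3 CPM, with 60.5 CPM in KO TGFb replicate 2. In all, 6970 genes passed, 3462 higher and 3508 lower in KO cells, 3494 of them at least 2-fold. Removing KO TGFb replicate 2 gave 9716, 4783 higher and 4933 lower, and removing replicate 1 or 3 of every group 4380 or 4129.

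Of 25 TGFb-SMAD target genes 24 were lower in KO cells and 1 higher by either adjustment (adjusted p = 1.13e-14, and adjusted p = 0.0482 with an estimated correlation), with Col7a1 at -7.49 ± 0.53 and Serpine1 at -3.94 ± 0.19. With the replicate block as well, the calls of this list (adjusted p = 0.0766), Hippo-YAP target genes (0.0766) and fibroblast markers (0.0521) were lost. Extracellular matrix genes were lower in 19 of 24 cases and higher in 2 by either adjustment (adjusted p = 2.88e-14), with Tnc at -7.89 ± 0.43, Col12a1 at -5.87 ± 0.26 and Fn1 at -3.06 ± 0.13. Mesenchymal genes were lower in 11 of 17 cases and higher in 1 (12 and 1 adjusted over the list alone; adjusted p = 1.74e-04), Itga5 at -3.79 ± 0.34 among them, and contractile genes in 11 of 14 and higher in 1 by either adjustment (adjusted p = 3.59e-04), with Acta2 at -4.72 ± 0.21 and Actn1 at -1.43 ± 0.09. Hippo-YAP target genes were lower in 7 of 15 cases and higher in 1 by either adjustment (adjusted p = 4.25e-04), with Ctgf at -3.31 ± 0.16. TGFb family genes were lower in 13 of 27 cases and higher in 5 (13 and 6 adjusted over the list alone; adjusted p = 0.0163, and adjusted p = 0.0588 with an estimated correlation). Bmp1 stood at -3.25 ± 0.17 and the activin subunit Inhba at -2.62 ± 0.12. Basal and squamous genes were lower in 6 of 9 cases and higher in 1 by either adjustment (adjusted p = 0.0117, and adjusted p = 0.0502 with an estimated correlation), Krt14 844 times lower (95% counting interval 233 to 6980) and Lamb3 at -4.82 ± 0.32. Cholesterol and fatty acid synthesis genes were lower in 15 of 26 cases and higher in 1 by either adjustment (adjusted p = 0.0163, and adjusted p = 0.155 with an estimated correlation). Among them the LDL receptor Ldlr stood at -0.90 ± 0.16 and Pcsk9, which degrades that receptor, was 43.1 times lower (95% counting interval 11.5 to 362). In the fit without KO TGFb replicate 2, 9 Hippo-YAP target genes were lower and 3 higher, and 20 cholesterol and fatty acid synthesis genes lower and 2 higher. Higher TGFb family genes were 3 with any 1 of the EV TGFb libraries left out, and higher Hippo-YAP target genes 2 without KO TGFb replicate 1 or 3. The higher cholesterol call was lost without EV TGFb replicate 1 or 2, and 2 basal genes were higher without EV TGFb replicate 1.

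Replication and mitosis genes were higher in 33 of 34 cases and lower in none (34 and 0 adjusted over the list alone; adjusted p = 2.09e-29), with Kif11 at 3.37 ± 0.19, Cdc6 at 3.19 ± 0.20, Hells at 3.11 ± 0.34 and Birc5 at 3.06 ± 0.25. Chemokine and cytokine genes were higher in 9 of 19 cases and lower in 5 by either adjustment (adjusted p = 0.0185, and adjusted p = 0.0553 with an estimated correlation). Ccl20 (7.56 ± 0.68), Cxcl5 (5.58 ± 0.41) and Cxcl3 (0.333 ± 0.252 CPM in EV and 15.9 ± 2.73 CPM in KO cells) were higher, and Il11 stood at 27.6 ± 12.3 CPM in EV and 0.0592 ± 0.057 CPM in KO cells. BMP-ID target genes were higher in 4 of 7 cases and lower in 2 by either adjustment (adjusted p = 0.526 for the list), with Hey1 at 5.72 ± 0.34 and Id3 at -4.35 ± 0.23. Classical pancreatic cancer and ductal genes were higher in 9 of 18 cases, the lectin Lgals4 (4.31 ± 0.33) among them, and lower in 4, with Sox9 at -2.70 ± 0.13, by either adjustment (adjusted p = 0.709 for the list). Psat1 was higher at 2.42 ± 0.12. The epithelial list had an adjusted p of 0.112, and of 0.0313 (higher) without KO TGFb replicate 2 (adjusted p = 0.1535 with an estimated correlation).

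Ass1, the enzyme that makes argininosuccinate, Adam12, a metalloprotease, and Rftn1 had no counts in KO cells with TGFb and were at least 559-fold, 288-fold and 334-fold lower than in EV cells. Crlf1, a cytokine receptor-like factor, stood at 202 ± 21.9 CPM in EV and 0.0425 ± 0.0737 CPM in KO cells. Dapk1 was at least 192-fold higher in KO cells, and the transporter Slc43a3 stood at 0.0685 ± 0.0806 and 49.6 ± 2.61 CPM. Fibroblast and stellate cell markers were lower in 4 of 5 cases and higher in none by either adjustment (adjusted p = 4.25e-04), and the endothelial marker Cdh5 had no counts in KO cells and was at least 153-fold lower (2 of 5 endothelial markers lower by either adjustment, and 2 lower and 1 higher without KO TGFb replicate 2; adjusted p = 0.0953).

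The authors' deposited tables list their own comparisons for 3 of these contrasts. Of 7030 genes that the authors' deposited table calls for TGFb in EV cells, 6855 were tested here, 3836 passed in the same direction and 6909 did without KO TGFb replicate 2. Of 133 that the authors' deposited table calls for TGFb in KO cells, all were tested here, 115 passed and 132 did without that library. Of 2126 in the authors' deposited table of untreated KO against EV cells, 1920 were tested here, 1728 passed and 1962 did without that library. Fits without it tested 14551 genes. No gene called in an authors' deposited table was called in the opposite direction here.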

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

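The tests of a mislabelled library, of the sources of the genes called in KO cells and of a copy number difference were chosen only after the result was seen, and the values without KO TGFb replicate 2 also came after.

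The TGFb responses of KO and EV cells differed by the interaction test for 1618 genes. The log2 differences, KO minus EV, were positive for Alb (8.24), Apoa1 (7.14), Sptssb (6.64), Hal (5.83), Cxcl5 (5.22), Ccl20 (5.16), Atoh8 (4.89), Hey1 (4.51), Anxa10 (3.24), Muc1 (2.64), Egln3 (2.12), Id1 (2.10), Birc5 (1.92), Id2 (1.90), Kif11 (1.90), Cdc6 (1.73), Ocln (1.56), Cdkn1a (1.33), Mylk (1.24) and Pdk1 (0.99). They were negative for Col7a1 (-6.45), Tnc (-3.79), Col12a1 (-2.99), Acta2 (-2.86), Itga5 (-2.80), Serpine1 (-2.70), Fstl3 (-2.22), Ltbp1 (-2.22), Wnt7b (-2.21), Ctgf (-2.06), Sox9 (-1.98), Cyr61 (-1.56), Fn1 (-1.18) and Hmgcr (-1). Among lists, the responses differed for TGFb-SMAD target genes (adjusted p = 2.81e-17), extracellular matrix (1.44e-16), replication and mitosis (2.00e-15), BMP-ID target genes (3.88e-06), Hippo-YAP target genes (2.11e-04), glycolysis and hypoxia (8.24e-04, and 0.254 with an estimated correlation), mesenchymal genes (0.0011), classical pancreatic cancer and ductal genes (0.0013), contractile genes (0.0045), chemokines and cytokines (0.0072, and 0.0764 with the replicate block), cholesterol and fatty acid synthesis (0.0094, and 0.131 with an estimated correlation), Wnt target genes (0.0228, and 0.0725 with an estimated correlation) and epithelial genes (0.0258, and 0.241 with an estimated correlation). With an estimated correlation, the first 3 of these lists had an adjusted p of 0.0301 each and BMP-ID target genes of 0.0464. With the replicate block as well these 4 were 0.0862, 0.0641, 0.0641 and 0.1078, and none of the 13 list calls held. The block at the preset correlation kept 12 of the 13.

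Other splits of the libraries bear on the counts. For TGFb in EV cells, TGFb in KO cells, and KO against EV cells without and with TGFb, 10 splits of 6 libraries exist, so a share under 0.05 cannot be reached. The real splits gave 3886, 145, 4740 and 6970 genes, 1 split of 10 in each case, and the highest of the others gave 0, also among the 4 splits that part all 3 pairs. For the difference in response, 10 of 100 splits gave at least the 1618 genes of the real one, with 1939 in the highest other. Those 10 keep the EV libraries as labelled and range from 1618 to 1939 genes, while the 90 splits that regroup the EV libraries gave 0, and the highest among the 16 that part all pairs was 1939. The response of EV cells alone thus gives a count of this size however the KO libraries are grouped, so these splits do not show whether the difference arose by chance.

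KO TGFb replicate 2 detected fewer genes and spread more than the other libraries. Lower depth is argued against, since other libraries thinned to its total detected at least 22.2% more genes. A wrong label on an EV library is argued against by its Smad4 level of 7.87 CPM, 7.72% of the lowest EV library. Few starting molecules could account for it, as the SD of its deviations from the other replicates, corrected for GC content and length, was 4.29 times the largest of any other library. That SD measures the same spread that set the library apart, so it cannot tell few molecules from another cause. Bias by GC content and gene length accounted for 44.6% of the variance of its deviations against up to 19.1% elsewhere, which leaves open whether it is a cause or a part of the same fault, and no biological explanation was tested.

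Genes called for TGFb in KO cells held members of the TGFb-SMAD list. KO TGFb replicate 2 is argued against as their source, since 100% of the 145 were called in the same direction without it. RNA of EV TGFb libraries or cells is argued against, because 34 genes near 0 in untreated KO cells stood in KO TGFb libraries at a median of 0.133% of their EV TGFb level (1.08% pooled, 16.5% for the highest gene), where the called genes would need a median of 19.7%. For cells with intact Smad4 among the KO cells, the Smad4 level would call for 7.23%, against that same 0.133% and the pooled 1.08%. Genes counted in untreated EV cells, such as Plagl1 (13.2 CPM) and Afap1l1 (11.3 CPM), cannot test this. Such cells would have kept them from being near 0 in untreated KO cells. The genes below 1 CPM in untreated EV cells argue against it, at 1.15% or less for all but Trbc1 (8.69%). A response to TGFb without full Smad4 stays open as a hypothesis, and the transcripts left of Smad4 were not examined for function.

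Genes of chromosome 19 were higher in KO cells as a whole. Bias by GC content and gene length is argued against by a median of 0.75 after correction, and a few strongly changed genes by the 92.8% of 375 genes that were higher. A copy number difference between the KO and EV cells could account for it, since the lowest median of its 3 parts was 0.56 (part 1 with TGFb, 0.79 without KO TGFb replicate 2) and TGFb moved its median by -0.01 in EV and -0.09 in KO cells. By parts, TGFb moved the medians in KO cells by -0.22, 0.08 and -0.06, where that of part 1 exceeds the 0.15 set as a limit for the whole chromosome, and by 0.02, -0.02 and -0.02 without KO TGFb replicate 2. The copy number difference stays a hypothesis found and tested on the same data, and DNA was not measured.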

How the results depend on the processing

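The fits without KO TGFb replicate 2, with sample weights, with robust dispersions and with GC and length correction were added after the data were seen. Counts kept within 1.5 times their reported value with RLE scaling, library totals, 2 other filters, limma voom and robust dispersions. With only the libraries compared, TGFb in EV cells gave 7540 genes, TGFb in KO cells 1, untreated KO against EV 8907 and KO against EV with TGFb 4405. By construction, that setting leaves fewer libraries to estimate the spread and keeps KO TGFb replicate 2 only in the fits of TGFb in KO cells and of KO against EV with TGFb. A threshold of 2-fold gave 1649, 67, 903, 1757 and 3494 genes for TGFb in EV cells, in KO cells, their difference, and KO against EV without and with TGFb, since it only removes genes. DESeq2 gave 512 for TGFb in KO cells and 2466 for the difference, and GC and length correction 248 and 2574, and the cause was not tested. Sample weights gave 7767 for EV cells, 1832 for KO cells, 5394 for the difference and 9454 for untreated KO against EV. Leaving out libraries or batches gave 1386 to 8031 for EV cells, 1 to 1344 for KO cells, 116 to 5088 for the difference, 1612 to 9047 and 4129 to 9716 for KO against EV without and with TGFb, each highest count without KO TGFb replicate 2. Without replicate 1 or without replicate 3, where KO TGFb replicate 2 was 1 of 2 libraries of its group, TGFb in KO cells gave 1 gene.

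With the replicate number as a block, TGFb in KO cells gave 72 genes, and the other counts stayed within 1.5 times (3528, 1263, 4331 and 6572). The block and the removal of KO TGFb replicate 2 together gave 7817, 964, 4631 and 8827 for TGFb in EV cells, in KO cells, the difference and untreated KO against EV. The block ended the list calls for chemokines in EV cells, the difference and untreated KO against EV, and for BMP-ID and classical genes in untreated KO against EV. It added replication genes in KO cells and the TGFb family in untreated KO against EV. At the preset correlation it changed no other list call, and it changed none of the 185 calls among the 189 gene results named.

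Of these 185 calls, all were kept with RLE scaling, library totals, no filter and DESeq2, 184 with voom (without Ccl20 in the difference, adjusted p = 0.0611), 136 of 151 with only the libraries compared, 181 to 185 without any 1 library, and 143, 185 and 147 without replicate 1, 2 and 3. Smad4 in KO cells, -0.08 and not called, ran from -0.20 to 0.04 with a replicate number left out, 0.04 being without replicate 2, and was 0.02 without KO TGFb replicate 2. In EV cells, where it was not called, it passed as higher with RLE scaling (adjusted p = 0.0372), a mean CPM of at least 1 (0.0401), DESeq2 (0.0017), voom (0.0229), only the libraries compared (0.0011), without replicate 2 (0.0031) and without KO TGFb replicate 2 (1.79e-04). Its difference in response passed without KO TGFb replicate 2 (adjusted p = 0.0463).

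Of 58 list calls, 30 held with an estimated correlation, 16 higher and 14 lower. With the replicate block as well, an alternative added after the data were seen, 10 held, 6 in EV cells and 4 in KO against EV with TGFb. None held in KO cells (lowest adjusted p = 0.1228), the difference (0.0641) or untreated KO against EV (0.0712). An estimated correlation without KO TGFb replicate 2 kept 28, and none in untreated KO against EV (0.0892), also an alternative added later. The fry test of limma asks whether a list changes at all, not whether it changes more than other genes. It kept 12 of 12 calls in EV cells, 8 of 10 in KO cells and 13 of 13 in the difference. In KO against EV cells it kept 12 of 12 without and 11 of 11 with TGFb. It also called lists that camera had not, such as 8 in EV cells. The 30 held with an estimated correlation alone were TGFb-SMAD, mesenchymal, extracellular matrix, contractile, replication and Hippo-YAP genes in EV cells, the difference and KO against EV with TGFb; TGFb family and Wnt genes in EV cells; TGFb family, classical and basal genes in KO cells; BMP-ID, chemokine and classical genes in the difference; replication and basal genes in untreated KO against EV; and fibroblast markers in KO against EV without and with TGFb. Directions turned only for lists that did not pass before: p53 genes with fry in KO against EV without (adjusted p = 0.3685) and with TGFb (0.5721), with the block in the difference (0.9355) and untreated KO against EV (0.8999), and without KO TGFb replicate 2 in KO against EV without (0.8212) and with TGFb (0.8792). Without that library they also turned for antigen presentation in EV cells (0.9935), KO cells (0.9494) and the difference (0.8471), for BMP-ID (0.0093) and epithelial genes (0.9510) in KO cells, for endothelial markers in KO cells (0.2352) and the difference (0.7542), and for acinar and islet markers there (0.8825 and 0.9667). The median, mean and test differed in sign for epithelial genes in the difference (not without KO TGFb replicate 2, with 0.80 and 0.34) and for some lists that did not pass, such as p53 genes.

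The responses of EV and KO cells correlated at 0.37 among genes with at least 10 CPM and 0.355 without KO TGFb replicate 2, against 0.295 over all tested genes, and without that library 645 genes were higher and 415 lower in both. The KO effect measured with TGFb correlated with the EV response at -0.672, and at -0.681 without that library, against -0.089 untreated. Simulated unchanged groups sharing the EV TGFb libraries gave -0.503 and -0.464. With no true change in these groups, their correlations do not show how much of -0.672 or -0.681 the shared libraries account for. The covariance was -1.086 against a simulated -0.0663, and -1.138 against a simulated -0.0253 without that library. Of the 54532 genes, 14234 had enough counts to be tested, and the effect of depth on that number and on recovery was not tested. Recovery of simulated 2-fold changes was 54% at the spread that KO TGFb replicate 2 widened for all libraries, and 78% without it. The simulation changed far fewer genes than were called for TGFb in EV cells.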

Other observations

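The chromosome 19 shift held along the chromosome. In untreated cells the medians of its 3 parts of 125 genes were 0.76, 0.78 and 0.71, and with TGFb 0.56, 0.89 and 0.77. Without KO TGFb replicate 2 the medians with TGFb were 0.79, 0.80 and 0.77. Chromosome 5 had a median of 0.22 in untreated KO against EV cells and chromosome 13 of 0.16. Smad4 lies on chromosome 18.

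The first 3 principal components held 56.9%, 21.6% and 12.5% of the variance, and 67.5%, 18.8% and 2.3% without KO TGFb replicate 2.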
